A study of Mus musculus with 36 samples.

How the data were processed

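Gene expression was measured with a one-colour Illumina bead array for mouse in 36 samples: 8 OSE, 11 OSK and 11 OSKT iPS clones, 4 replicates of R1 ES cells and 2 of D3 ES cells. The labels give total RNA purified on silica columns, labelled as biotinylated cRNA and read with BeadStudio, with no version given. The authors deposited signal intensities that had not been scaled between arrays, in which a background had already been subtracted within each array, since 25.4% to 29.6% of measured probes lay below 0. They also deposited a scaled table, whose intensity values were the same signals raised to a floor of 20 and then scaled between arrays by a factor that varied with intensity. The unscaled intensities were analysed here, and the scaled table served as an alternative.

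Of the 24613 probes in the deposited table, 5893 (23.9%) held values between -5.3 and 14.7 on every array that did not correlate between arrays (highest correlation 0.0376) and followed a uniform distribution. They were taken as placeholders without a measurement and left out, which leaves 18720 measured probes and means that some genes could not be read by all their probes (3824 symbols had such a probe, and 3588 of these also had a measured one). Probe symbols came from the supplied annotation, with 20984 probes on 1 symbol, 1 on several and 3628 on none.

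Signals were background-corrected with the normal-exponential model (saddle-point estimate, offset 16), quantile-normalized and put on the log2 scale in limma 3.58.1 under R 4.3.3. A correction by control probes had been planned, but the deposited table has neither control probes nor detection p-values. The background of each array was therefore estimated from its negative signals, and a probe counted as above background where its signal passed the 99th percentile of a normal distribution of that spread (45.2 to 90.8 intensity units). Probes above background on at least 4 arrays were kept (10572), and the probe with the highest mean was taken for each gene, which gave 10533 features, 9235 of them with a symbol. Between 8675 and 9720 probes were above background per array. The arrays' number sets the precision, which was tested on simulated data with 100 features changed by a log2 of 0.5 and 100 by 1. The fit recovered 87% of log2 changes of 0.5 for OSKT against OSK, 63% to 82% for the other comparisons of iPS clones and 32% for D3 against R1, and 87% to 100% of changes of 1. The simulated arrays were independent, unlike near-identical clones, so these shares may be too high for the real data.

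A linear model with 1 mean per group over all 36 arrays was fitted with limma (moderated variance with an intensity trend). The comparisons were OSKT with OSK, OSE with OSK, each iPS set with R1, and D3 with R1. P-values were 2-sided and adjusted by Benjamini-Hochberg over features, and an adjusted p under 0.05 was called changed. Clones were treated as replicates, though some were nearly identical. A fold whose lower group had no array above background was computed against the lowest normalized signal above background on each array and given as a bound. The same floor was used where some but no more than 50% of its arrays were above background, a choice made after the values were seen.

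Gene lists were fixed from general knowledge before the data were examined: pluripotency, germ cell, fibroblast, endoderm, mesoderm and primitive streak, neural ectoderm, primed epiblast, trophoblast, the Dlk1-Dio3 imprinted region, other imprinted genes, the 2-cell-like state, Y-linked genes, X inactivation, DNA methylation and Polycomb, p53 targets, interferon response, targets of LIF and Stat3, glycolysis and hypoxia, integrated stress response, cell cycle and cholesterol synthesis. Lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation (statmod 1.5.0), adjusted over the lists of a comparison. Some lists share members, such as Rhox6, Rhox9 and Tfap2c for germ cells and trophoblast, and Dnmt3a and Dnmt3b for the primed epiblast and DNA methylation. Members were also counted with p adjusted over the list alone.

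The genes named were set by a rule that was fixed at the same time: the 8 highest and 8 lowest called genes with an informative symbol, the factor genes, up to 4 members with the smallest p per described list, and Meg3, Xist and Y-linked genes. Of these last, Eif2s3y alone passed the filter, and Meg3 and Xist were not tested. X-linked genes, clone numbers and the Y chromosome in single clones were examined after their values were seen. Similarity was the Pearson correlation across features with the mean of the R1 arrays, and spread the root mean square difference from the other clones of a set. Both were compared between sets by permutation of clones, with all splits where a group had under 10 and 1e+05 draws otherwise.

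Alternatives were the scaled table, scaling to a common median, no background correction, no or a stricter filter (18 arrays), every probe as a feature, only the compared groups, array weights, replicate number as a block, the Y-linked or the fibroblast signal as a covariate, both ES lines as reference and leaving out each array. Added after the data were seen were keeping placeholder probes, averaging near-identical arrays, clone numbers 1 to 4 against 5 and above as a term, these ranges alone, leaving out X-linked features, and the fibroblast list mean as a covariate for similarity. Replicate numbers did not pair clones across sets: deviations from the group mean correlated above 0.1 for 9 of 11 OSKT and OSK pairs of equal number, but equal numbers were the best match for 2 of 11, so the fit has no block. R1 cells have replicates 1 to 4 alone. The replicate block and the clone-number term thus set R1 cells mainly against iPS clones 1 to 4. A slide block was not run, as neither labels nor column names give the slide.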

Results

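Gene expression was measured with a one-colour Illumina bead array for mouse in 36 samples. Of these, 30 were clones of induced pluripotent stem (iPS) cells made from mouse embryonic fibroblasts with 1 of 3 sets of reprogramming factors. The OSE set (Oct4, Sox2 and Esrrb) had 8 clones, the OSK set (Oct4, Sox2 and Klf4) had 11, and the OSKT set (Oct4, Sox2, Klf4 and Tbx3) had 11. Embryonic stem (ES) cells were the line R1 with 4 replicates and the line D3, grown in a medium for embryonic fibroblasts, with 2. Between 8675 and 9720 of the 18720 measured probes (46.3% to 51.9%) stood above background on each array, and the 75th percentile of the signal per array ran from 337.3 to 1056.7 intensity units. The number of arrays limits the precision of every value. Some clones of a set were as alike as the R1 replicates were to each other (7 of the 55 OSK pairs, 6 of the 55 OSKT pairs and 3 of the 28 OSE pairs). Arrays linked by such pairs form near-identical clusters, which leave 6 OSK, 6 OSKT, 5 OSE and 1 R1 sample when each is averaged. Most clones may thus not be independent. The p-values count each clone as 1 sample and measure the spread between these samples. Values are normalized log2 signals with the SD between samples, "changed" means a Benjamini-Hochberg adjusted p under 0.05 in the limma fit of 10533 features, and each gene rests on 1 probe unless stated. Where every array of a group lay below background, the fold is given as a lower bound computed from the detection limit. Where most arrays of the dimmer group did, "at least" gives the fold with each of its arrays raised to that limit.

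The comparison of OSKT with OSK clones asks what the addition of Tbx3, a T-box transcription factor of the pluripotency network, went with. The genes with the largest rise were Tmtc3, an enzyme of protein O-mannosylation, at least 3.63-fold higher (adjusted p = 2.31e-07, above the OSK mean in 10 of 11 clones, and above background in 9 of 11 OSKT and 2 of 11 OSK clones), and the cancer/testis gene Ct55, at least 2.84-fold higher (adjusted p = 8.3e-08, 11 of 11 clones). They were followed by Dnajc5g, a co-chaperone (2.77-fold), Lst1, a gene of the major histocompatibility region (2.48-fold), Smtnl1, a regulator of muscle contraction (2.47-fold), Apom, an apolipoprotein (2.42-fold), and the oocyte homeobox gene Obox6 (2.32-fold), each above the OSK mean in 11 of 11 clones. Btk, a tyrosine kinase of B cells, was at least 1.03-fold higher, being below background in 11 of 11 OSK clones. The genes with the largest fall by the fitted difference were Npy, a neuropeptide (at least 1.69-fold lower, below the OSK mean in 11 of 11 clones), the epithelial keratins Krt8 (2.25-fold lower, 7 of 11) and Krt18 (1.96-fold lower, 8 of 11), Acta1, skeletal actin (2.16-fold lower, 9 of 11), and the imprinted inhibitor of cyclin-dependent kinases Cdkn1c (1.98-fold lower, 9 of 11). Sugt1, a co-chaperone of Hsp90, was 2.01-fold lower, Kpna3, a nuclear import receptor, 1.93-fold lower, and Gipc2, a PDZ protein, 1.89-fold lower, each in 11 of 11 clones.

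Of the 5 tested genes of the reprogramming factors, Pou5f1 alone passed the test between OSKT and OSK clones. Tbx3 itself read 10.88 ± 0.31 in OSKT and 10.77 ± 0.23 in OSK clones (SD, n = 11 each, adjusted p = 0.557 from limma), and whether its probe also reads the transgene is not known. Pou5f1, the gene of Oct4, rose 1.24-fold (adjusted p = 0.00472, 9 of 11 clones above the OSK mean). Its log2 difference was 0.22 within clones 1 to 4, which did not pass (adjusted p = 0.108), and 0.35 within clones 5 to 11 (adjusted p = 2.22e-05). Sox2 (adjusted p = 0.903), Klf4 (adjusted p = 0.433) and Esrrb (adjusted p = 0.586) did not pass the test, and the Myc probe was too dim to be tested. Within clones 1 to 4 and within clones 5 to 11 the log2 differences had opposite signs: -0.38 and 0.39 for Tbx3, -0.39 and 0.47 for Klf4, and -0.32 and 0.21 for Sox2. Of these, Klf4 in clones 5 to 11 passed (adjusted p = 0.0109, with 0.0109 to 0.709 over all settings tried), and the change between the ranges was not tested.

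Among 30 tested genes of pluripotency, 9 rose in OSKT clones, none fell and 21 did not pass, and adjusted over the list alone 9 rose. Those that rose included Fgf4, a growth factor of the inner cell mass (1.92-fold), Tcl1, a co-activator of Akt (1.53-fold), Gdf3, a ligand of the TGF-beta family (1.20-fold), and Trim28, a co-repressor (1.17-fold). Of 22 germ cell genes, 9 rose, 1 fell and 12 did not pass (10 rose and 1 fell adjusted over the list alone). They included the testis tubulin Tuba3a (2.14-fold), the testis paralog of a general transcription factor Taf7l (1.46-fold), and the interferon-induced membrane proteins Ifitm1 and Ifitm3 of early germ cells (1.17-fold each). Of 5 tested genes of the 2-cell-like state, 3 rose (3 adjusted over the list alone), with Tdpoz1 at least 1.15-fold, Tcstv3 1.59-fold (log2 0.67, and 0.84 on a second probe) and Zfp352 1.21-fold higher. Both tested genes of the imprinted Dlk1-Dio3 region passed (2 adjusted over the list alone): Dlk1, a Notch-like ligand, rose 1.51-fold in 11 of 11 clones. Dio3, a deiodinase, was above background in 3 of 11 OSKT and 1 of 11 OSK clones, so no fold is given. Of 20 trophoblast genes, 5 rose, 6 fell and 9 did not pass (5 rose and 7 fell adjusted over the list alone), with Ascl2 1.32-fold and Tead4 1.24-fold higher beside the lower keratins. None of the 18 lists that could be tested as sets passed in camera: 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.218, for the germ cell genes (0.898 with an estimated correlation). Of the genes named from these lists, Tuba3a and Taf7l passed within clones 1 to 4 too, and the others did not. Their log2 differences there were 0.39 for Fgf4, 0.37 for Tcl1, 0.19 for Trim28 and 0.04 for Gdf3. They were 0.12 for Ifitm1, 0.05 for Ifitm3, 0.21 for Tdpoz1, -0.01 for Tcstv3, -0.07 for Zfp352, 0.22 for Dlk1, 0.46 for Ascl2 and 0.29 for Tead4. With near-identical arrays averaged, Fgf4 (0.83), Tcl1 (0.47), Gdf3 (0.25), Taf7l (0.35), Tcstv3 (0.71), Ascl2 (0.34) and Tead4 (0.24) no longer passed.

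Genes on the X chromosome stood higher in OSKT than in OSK clones. Of 295 tested X-linked genes, 147 rose and 8 fell, with a median log2 difference of 0.21, whereas of 8935 autosomal genes 1669 rose and 1476 fell. The median of the X-linked genes over that of the autosomal genes, each against the R1 mean, was 0.41 ± 0.10 per array in OSKT and 0.20 ± 0.09 in OSK clones (SD, n = 11 each, 2-sided permutation p = 0.0002). The difference was 0.03 within clones 1 to 4 and 0.31 within clones 5 to 11, and these 2 values differed (by 0.28, permutation p = 0.0003). From clones 1 to 4 to clones 5 to 11 the mean went from 0.26 to 0.16 in OSK and from 0.29 to 0.47 in OSKT. Both permutations count near-identical clones as separate units, so their p-values are too small to the extent that such clones are not independent. OSK clones 1 to 4 all fell in the same near-identical cluster, and the ranges were set after the values were seen. The Y-linked gene Eif2s3y was above background in 0 of 11 OSKT clones and 1 of 11 OSK clones.

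**Figure D1:**
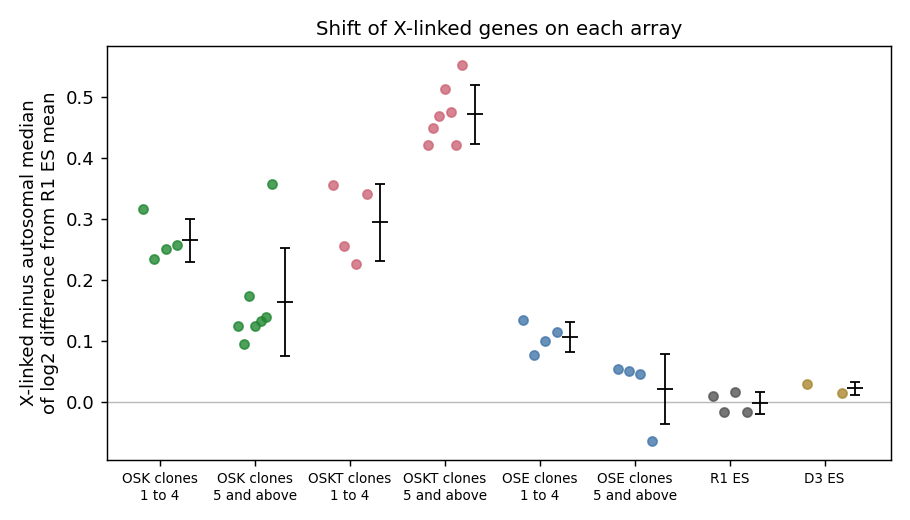
Each point is 1 array, and the vertical axis is the median log2 difference from the R1 mean of X-linked genes minus that of autosomal genes, with the mean and SD of each set of samples beside the points. OSKT clones 5 to 11 lie between 0.42 and 0.55, above the highest OSK clone of that range at 0.36, while clones 1 to 4 of both sets overlap.

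In all, 3741 of the 10533 features (35.5%) changed between OSKT and OSK clones, 2058 higher and 1683 lower, with a median absolute log2 difference of 0.31. A difference of at least 2-fold was found for 35, of which 30 were higher (28 and 5 lower with groups below background set at their bound). With arrays scaled to a common median, 2199 were higher and 1037 lower. Clones 1 to 4 of each set gave 1282 changed features and clones 5 to 11 gave 3972. In the lower range all OSK clones fell in the same near-identical cluster, and OSKT clones 1 and 4 were near-identical, as were clones 2 and 3. Calls within clones 1 to 4 thus rest on few distinct samples. Of the 16 genes with the largest changes, Ct55, Smtnl1, Sugt1 and Kpna3 passed within clones 1 to 4, where Tmtc3 had a log2 difference of 1.08 (adjusted p = 0.0718), against 2.62 in clones 5 to 11, and Cdkn1c one of 0.38 (adjusted p = 0.589), against -1.76. The keratins did not pass there: Krt8 had -0.17 (adjusted p = 0.739), against -1.74 in clones 5 to 11, and Krt18 -0.01 (adjusted p = 0.98), against -1.52. The others were at 0.34 for Dnajc5g, 0.41 for Lst1, 0.35 for Apom, 0.52 for Obox6, 0.37 for Btk, -0.25 for Npy, -0.88 for Acta1 and -0.31 for Gipc2 within clones 1 to 4. With near-identical arrays averaged as 1 sample, which leaves 6 OSKT and 6 OSK samples, 1362 features changed. Of the 41 named genes that passed, 16 no longer did, with SEs 1.26 to 1.68 times as large. Their log2 differences went from -1.17 to -1.16 for Krt8, -0.97 to -0.98 for Krt18, and -0.98 to -1.14 for Cdkn1c. They went from -1.11 to -0.73 for Acta1, -0.95 to -0.78 for Kpna3 and 0.30 to 0.26 for Pou5f1.

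OSK clones were compared with R1 ES cells to show how far clones made without Tbx3 stood from ES cells. The keratins Krt8 and Krt18 were 35-fold and 21.8-fold higher, and the X-linked homeobox genes Rhox9 and Rhox6, of germ cells and placenta, were 25.3-fold and at least 14.7-fold higher. Dppa3, a maternal factor and germ cell marker, stood at 11.44 ± 0.28 in OSK clones (n = 11) and 7.09 ± 0.07 in R1 cells (n = 4), a 20.4-fold rise (limma adjusted p = 1.53e-26). Zfp42, the pluripotency marker also called Rex1, fell 33.6-fold, from 12.81 ± 0.07 to 7.74 ± 0.16 (adjusted p = 1.14e-27). The Y-linked Eif2s3y fell at least 17.5-fold and Erdr1, a gene of the pseudoautosomal region, at least 22.5-fold. They were above background in 1 and 3 of 11 OSK clones. Each of these held in 11 of 11 clones against all 4 R1 arrays. Eif2s3y was above background in 4 of 4 R1 arrays. Effects of reprogramming therefore cannot be told apart here from those of the sex or origin of the cells. Of 295 X-linked genes, 117 were higher and 37 lower in OSK clones, against 2289 and 2588 of 8935 autosomal genes.

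Other large rises in OSK clones were of Baiap2l1, an actin-bundling adaptor (25.8-fold), Rpl29, a ribosomal protein (17.8-fold), and Haus1, a subunit of the augmin complex (at least 14.7-fold). Other large falls were of Thumpd1, a factor of tRNA acetylation (28.4-fold), the chemokine Cxcl1 (16.8-fold), the collagenase Mmp13 (log2 difference -4.26), the unconventional myosin Myo1f (at least 8.42-fold) and the protease inhibitor Spink10 (at least 7.63-fold). Of the factors, Klf4 fell 2.77-fold (adjusted p = 1.58e-07), Esrrb 1.68-fold (1.12e-05), Sox2 1.48-fold (0.000337) and Pou5f1 1.28-fold (0.00848), each below the R1 mean in 11 of 11 clones. With the fibroblast signal as a covariate Pou5f1 did not pass (log2 -0.36 and -0.15, SE 0.11 and 0.08). Tbx3 had a log2 difference of -0.40 that did not pass (adjusted p = 0.0587), though it passed without OSK clone 2 (-0.43, adjusted p = 0.0494) or without clone 11 (-0.45, 0.0329), with median scaling (-0.66, 0.00148), with these groups fitted alone (-0.40, 0.00596), with array weights (-0.40, 0.00807), with replicate number as a block (-0.59, 0.00783) and with clone numbers 1 to 4 against 5 and above as a term (-0.59, 0.00466). R1 cells have no replicate above 4, so the block and the clone-number term set R1 cells mainly against clones 1 to 4. The adjusted p of Tbx3 ran from 0.00148 to 0.926 over all settings tried.

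**Figure D2:**
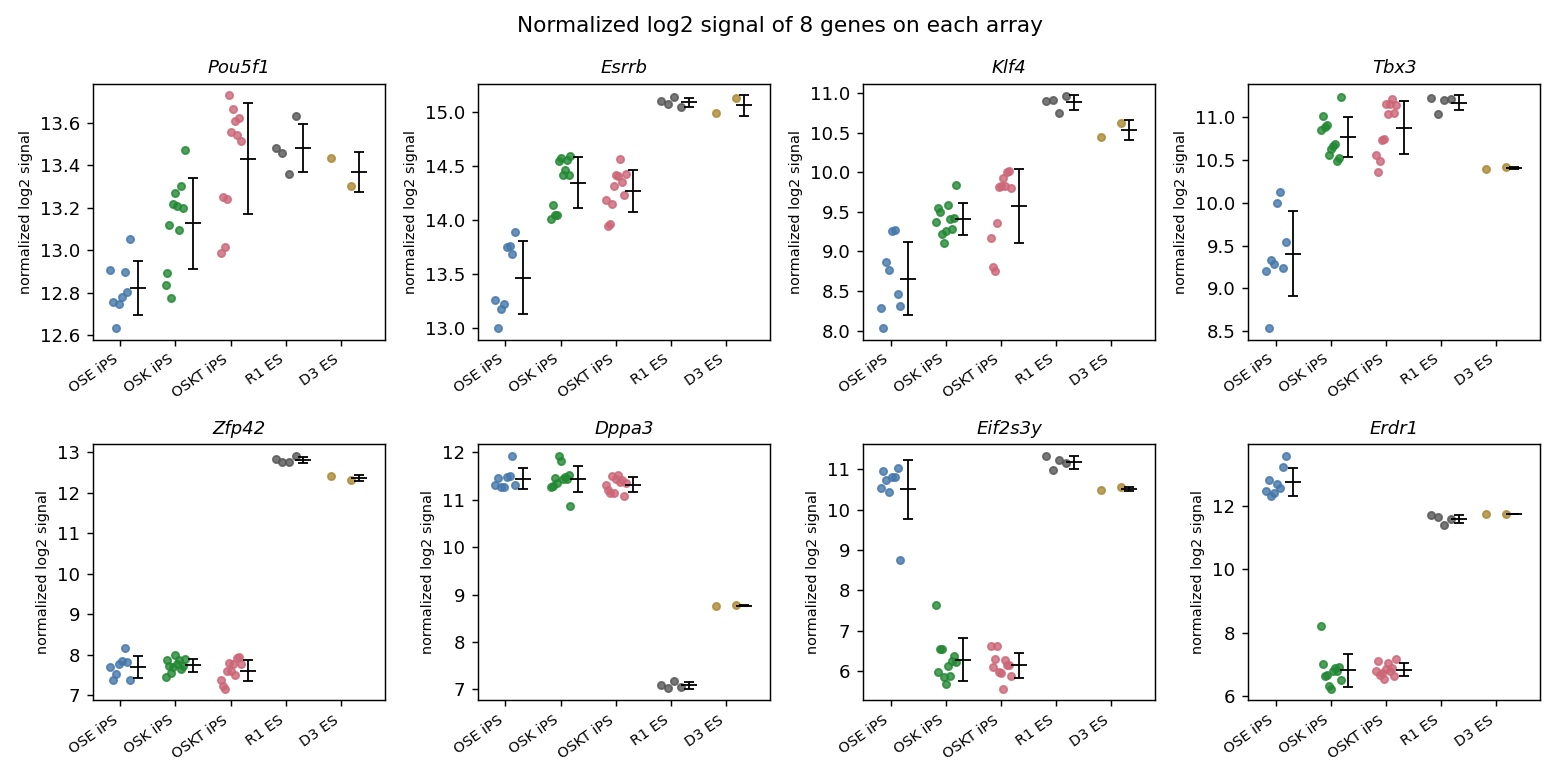
Each point is the normalized log2 signal of 1 gene on 1 array in the 5 groups, with the mean and SD of each group beside the points. Zfp42 and Dppa3 separate the iPS clones from R1 cells in opposite directions, and Eif2s3y and Erdr1 are near background in OSK and OSKT clones except for OSK clone 1, at 7.64 and 8.23.

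The pluripotency list fell in OSK clones: 20 of its 30 tested members fell, 3 rose and 7 did not pass (21 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.000406, adjusted p = 0.585 with an estimated correlation). The nuclear receptor Nr5a2 was 5.22-fold lower, whereas Sall4, a zinc-finger factor, was 2.39-fold higher. Targets of LIF and Stat3, the signal that holds mouse ES cells in self-renewal, fell for 12 of 17 and rose for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.0548 with an estimated correlation), with the feedback inhibitor Spry4 5.55-fold, Gbx2 4.85-fold and Klf5 2.54-fold lower. Genes of the integrated stress response fell for 16 of 22 and rose for 2 (16 and 2 adjusted over the list alone, camera adjusted p = 1.02e-05, adjusted p = 0.137 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, 15.1-fold and Trib3, a pseudokinase, 4.36-fold lower.

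Cholesterol synthesis rose in OSK clones, with 13 of 16 enzymes and regulators higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 1.83e-08, adjusted p = 0.0548 with an estimated correlation), among them Fdps 2.93-fold and Hmgcs1 2.58-fold. Trophoblast genes rose for 18 of 20 and fell for 2 (18 and 2 adjusted over the list alone, camera adjusted p = 1.83e-07, adjusted p = 0.136 with an estimated correlation), with the transcription factor Gata3 at least 3.47-fold higher. Genes of glycolysis and hypoxia rose for 12 of 19 and fell for 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.00526, adjusted p = 0.659 with an estimated correlation and 0.0698 with replicate number as a block, 0.00224 to 0.659 over the settings tried), with Ndrg1, a hypoxia-induced gene, 4.40-fold and the pyruvate kinase Pkm 1.87-fold higher. Endoderm genes rose for 9 of 19 and fell for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.659 with an estimated correlation), with the homeobox gene Rhox5 6.68-fold and the basement membrane collagen Col4a2 2.55-fold higher. Germ cell genes split, with 10 of 22 higher and 10 lower (10 and 10 adjusted over the list alone), a median log2 difference of -0.04, a mean of opposite sign, 0.37 (0.31 at their bound), an upward direction in camera and a camera adjusted p of 0.595. The RNA helicase Mov10l1 of the piRNA pathway was at least 3.15-fold lower and the transcription factor Tfap2c 2.84-fold higher. The mean of the fibroblast list, which marks the cells of origin, was 10.21 ± 0.44 in OSK clones and 9.72 ± 0.04 in R1 cells. It ran from 10.62 to 10.82 in OSK clones 1 to 4 and from 9.64 to 10.13 in OSK clones 5 to 11. The list did not pass (14 of 26 higher, 1 lower, camera adjusted p = 0.0612, but 2.54e-05 with replicate number as a block, 2.54e-05 to 0.734 over the settings tried). The block sets R1 cells mainly against clones 1 to 4, in which the list mean was higher.

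Between OSK clones and R1 cells 5664 features (53.8%) changed, 2720 higher and 2944 lower, and 951 by at least 2-fold, 489 higher and 462 lower (435 and 409 at their bound). Scaling to a common median gave 1777 higher and 3969 lower, with the median of all features moved to -0.12. With near-identical arrays averaged, which leaves R1 as 1 sample, 2391 changed. Pou5f1 (log2 -0.36 and -0.29), Sox2 (-0.57 and -0.57), Esrrb (-0.75 and -0.66) and Col4a2 (1.35 and 1.32) no longer passed, with SEs 1.85 to 1.93 times as large.

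OSKT clones were set against the same R1 cells to show where clones with Tbx3 stood. Baiap2l1 rose 32.9-fold, Rhox9 22.4-fold, Rpl29 21.2-fold, Dppa3 18.8-fold and Krt8 by 3.96 on the log2 scale, while Rhox6 was at least 11.2-fold higher. Slc4a3, an anion exchanger, rose 14.0-fold and Nod1, a sensor of bacterial peptidoglycan, 11.2-fold. Zfp42 fell 36.9-fold (adjusted p = 6.08e-28), to 7.61 ± 0.26, and Thumpd1 32-fold. Eif2s3y was at least 18.3-fold lower, Erdr1 at least 23.8-fold lower, Spink10 at least 7.62-fold, Myo1f at least 8.41-fold, the olfactory receptor gene Olfr887 at least 9.13-fold and Cxcl1 12.8-fold lower. All of these held in 11 of 11 clones. As for OSK clones, the sex or origin of the cells cannot be told apart from reprogramming here. Of 295 X-linked genes, 170 were higher and 25 lower than in R1 cells, against 2290 and 2597 of 8935 autosomal genes. Klf4 fell 2.48-fold (adjusted p = 1.26e-06), Esrrb 1.77-fold (2.28e-06) and Sox2 1.46-fold (0.000484). Pou5f1 (log2 -0.05, adjusted p = 0.72) and Tbx3 (-0.29, adjusted p = 0.172) did not pass against R1 cells. Both passed with replicate number as a block (-0.27, 0.0133 and -0.48, 0.0283). They also passed with clone numbers 1 to 4 against 5 and above as a term (-0.26, 0.00541 and -0.48, 0.0203). Both settings set R1 cells, which have replicates 1 to 4 alone, mainly against clones 1 to 4. Tbx3 also passed with median scaling (-0.49, 0.0153). Over all settings tried the adjusted p ran from 0.00541 to 0.988 for Pou5f1 and from 0.0153 to 0.662 for Tbx3.

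Targets of LIF and Stat3 fell in OSKT clones for 12 of 17 and rose for 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000149), and this call held with an estimated correlation (adjusted p = 0.0233). Spry4 was 5.92-fold, Gbx2 5.67-fold and Klf5 2.53-fold lower. The pluripotency list fell for 15 of 30 and rose for 3 (17 and 3 adjusted over the list alone, camera adjusted p = 0.00815, adjusted p = 0.658 with an estimated correlation), with Nr5a2 5.06-fold lower and Sall4 2.43-fold higher. Stress response genes fell for 16 of 22 and rose for 0 (16 and 0 adjusted over the list alone, camera adjusted p = 2.96e-05, adjusted p = 0.172 with an estimated correlation), with Chac1 9.77-fold and Trib3 3.69-fold lower. Cholesterol genes rose for 12 of 16 and fell for 1 (12 and 1 adjusted over the list alone, camera adjusted p = 5.49e-07, adjusted p = 0.0753 with an estimated correlation), with Fdps 3.10-fold higher. Trophoblast genes rose for 17 of 20 and fell for 1 (17 and 1 adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.172 with an estimated correlation), with Gata3 at least 4.36-fold and the homeobox gene Dlx3 at least 4.77-fold higher. Glycolysis and hypoxia genes rose for 12 of 19 and fell for 4 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0446, adjusted p = 0.658 with an estimated correlation and 0.28 with replicate number as a block, 0.026 to 0.658 over the settings tried), with Ndrg1 4.59-fold and Pkm 2.02-fold higher. Endoderm genes rose for 6 of 19 and fell for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0478, adjusted p = 0.658 with an estimated correlation), with Rhox5 9.35-fold higher. The fibroblast list averaged 10.09 ± 0.39 in OSKT clones. It ran from 10.42 to 10.71 in OSKT clones 1 to 4 and from 9.62 to 9.91 in OSKT clones 5 to 11.

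For OSKT clones against R1 cells 5724 features (54.3%) changed, 2785 higher and 2939 lower, and 944 by at least 2-fold, 491 higher and 453 lower (434 and 407 at their bound). Median scaling gave 2027 higher and 3701 lower, with the median of all features at -0.10. Averaging near-identical arrays left 2454 changed features, and Sox2 no longer passed (log2 -0.55 and -0.53, SE 0.13 and 0.25).

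OSE clones, in which Esrrb took the place of Klf4, had more features changed from R1 cells (6179) than OSK (5664) or OSKT clones (5724). With the fibroblast signal, which was higher in OSE clones, as a covariate, the order turned over, with 5551 for OSE, 6162 for OSK and 6454 for OSKT clones. Krt8 rose 30.6-fold, Krt18 13.7-fold and Dppa3 20.5-fold, to 11.44 ± 0.22 (n = 8, limma adjusted p = 1.03e-25). Olig1, a transcription factor of oligodendrocytes, rose 25.6-fold, Haus1 at least 14.7-fold, Rpl29 14.2-fold and Baiap2l1 12.2-fold, and Eif3j1, a subunit of a translation initiation factor, was at least 7.9-fold higher. Zfp42 fell 34.7-fold (adjusted p = 7.46e-27). The X-linked genes Dmrtc1c1 and Rhox13 were at least 15.6-fold and 13.5-fold lower, Efhc2, also X-linked, was at least 10.4-fold lower, and the meiotic cohesin Smc1b was at least 11-fold lower. The peptidase Dpp4 fell 12.6-fold, Spink10 at least 7.39-fold and the interferon-induced Oas2 at least 4.81-fold. All of these held in 8 of 8 clones.

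All 5 tested factor genes fell in OSE clones: Klf4 4.67-fold (adjusted p = 5.34e-11), Tbx3 3.40-fold (6.67e-10), Esrrb 3.08-fold (3.19e-12), Sox2 1.97-fold (1.32e-07) and Pou5f1 1.58-fold (1.46e-05), each in 8 of 8 clones. With the fibroblast signal as a covariate, Pou5f1 did not pass (log2 -0.66 and -0.17, SE 0.12 and 0.10). Esrrb thus read lower than in R1 cells although it was among the factors used, and its probe's position against the transgene is not known. Eif2s3y read 10.50 ± 0.73 and 11.17 ± 0.15 in R1 cells, a log2 difference of -0.66 (adjusted p = 0.0473) that did not pass without clone 8 (-0.41, adjusted p = 0.106), without clone 1 (0.0559) or 4 (0.0618), or without any 1 of the R1 arrays (0.0553 to 0.11). Over all settings tried its adjusted p ran from 1.8e-05 to 1.

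Cholesterol synthesis genes rose for 16 of 16 (16 adjusted over the list alone, camera adjusted p = 1.63e-10), and the call held with an estimated correlation (adjusted p = 0.028). The synthase Hmgcs1 was 3.39-fold, Fdps 3.24-fold, Lss 2.88-fold and Cyp51 2.54-fold higher. The pluripotency list fell for 24 of 30 and rose for 4 (25 and 4 adjusted over the list alone, camera adjusted p = 2.34e-06, adjusted p = 0.36 with an estimated correlation), with Nr5a2 5.69-fold lower. Fibroblast genes rose for 21 of 26 and fell for 1 (22 and 1 adjusted over the list alone, camera adjusted p = 4.39e-05, adjusted p = 0.473 with an estimated correlation), with the matrix genes Col1a1 3.94-fold, Thbs2 3.80-fold and Col6a1 3.35-fold higher, and the list averaged 10.88 ± 0.40. Trophoblast genes rose for 15 of 20 and fell for 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.000833, adjusted p = 0.36 with an estimated correlation). Stress response genes fell for 14 of 22 and rose for 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00226, adjusted p = 0.36 with an estimated correlation), with the transcription cofactor Nupr1 4.24-fold and the cystathionine lyase Cth 4.05-fold lower. LIF and Stat3 targets fell for 11 of 17 and rose for 2 (11 and 2 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.224 with an estimated correlation), with Klf5 3.38-fold lower. Genes of the 2-cell-like state fell for 4 of 5 (4 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.36 with an estimated correlation), with Tcstv3 5.44-fold (log2 -2.44, and -1.02 on a second probe) and Arg2 at least 1.94-fold lower. Germ cell genes rose for 7 of 22 and fell for 10 (7 and 10 adjusted over the list alone, camera adjusted p = 0.325), with Tuba3a 6.62-fold and Taf7l 6.34-fold lower.

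OSE clones and R1 cells differed in 6179 features (58.7%), 3027 higher and 3152 lower, and in 1254 by at least 2-fold, 593 higher and 661 lower (523 and 579 at their bound). Median scaling gave 2458 higher and 3517 lower. With near-identical arrays averaged the number was 2921.

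The comparison of OSE with OSK clones sets Esrrb against Klf4 as the third factor, but the sets also differ in Y-linked signal. Eif2s3y was above background in 8 of 8 OSE and 1 of 11 OSK clones. Effects of the factors therefore cannot be told apart from those of the sex or origin of the cells. Erdr1 was at least 50.8-fold higher in OSE clones (12.76 ± 0.43, n = 8, against 6.82 ± 0.53, n = 11), Olig1 at least 33.4-fold, Olfr887 at least 32.8-fold and Eif2s3y at least 11.1-fold higher. The last 3 were above background in 1 of 11 OSK clones each. Thumpd1 was 12.9-fold, the LIM protein Csrp1 5.47-fold, the lipase Abhd16a 5.40-fold and the sterol oxidase Msmo1 5.15-fold higher. The X-linked imprinted gene Xlr3b, above background in 1 of 8 OSE clones, was at least 10.9-fold lower, Dmrtc1c1 at least 4.28-fold, Obox6 at least 4.41-fold, Smc1b at least 4.03-fold and Rhox5 4.86-fold lower. Rcsd1, a regulator of actin capping, was at least 4.15-fold, the adhesion molecule Jam2 4.74-fold and the muscle enzyme Fbp2 4.63-fold lower. All of these held in 8 of 8 OSE clones against the OSK mean, with adjusted p from 1.2e-27 for Thumpd1 to 1.84e-09 for Dmrtc1c1. Of 295 X-linked genes, 41 were higher and 114 lower, and the Y-linked Eif2s3y was above background in 8 of 8 OSE clones and in 1 of 11 OSK clones.

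Every tested factor gene was lower in OSE than in OSK clones: Tbx3 2.57-fold (adjusted p = 1.61e-09), Esrrb 1.84-fold (2.38e-08), Klf4 1.69-fold (0.00025), Sox2 1.33-fold (0.00126) and Pou5f1 1.23-fold (0.00641), each below the OSK mean in 8 of 8 clones. With the fibroblast signal as a covariate Pou5f1 (log2 -0.30 and -0.02, SE 0.09 and 0.07) and Sox2 (-0.41 and -0.20, SE 0.10 and 0.11) did not pass. Nor did Pou5f1 within clones 1 to 4 (-0.14) or Sox2 within clones 5 and above (-0.27). With median scaling Pou5f1 did not pass (-0.17, adjusted p = 0.118). Over all settings tried its adjusted p ran from 0.000502 to 0.85.

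Glycolysis and hypoxia genes were lower for 16 of 19 and higher for 0 (16 and 0 adjusted over the list alone, camera adjusted p = 7.2e-08, adjusted p = 0.415 with an estimated correlation), with Ndrg1 4.40-fold, P4ha2, a collagen hydroxylase, 1.88-fold and the growth factor Vegfa 1.67-fold lower. Germ cell genes fell for 14 of 22 and rose for 0 (15 and 0 adjusted over the list alone, camera adjusted p = 1.65e-05, adjusted p = 0.415 with an estimated correlation), with Taf7l 2.80-fold, Tuba3a 2.30-fold and the receptor Kit 2.12-fold lower. Trophoblast genes fell for 10 of 20 and rose for 0 (10 and 0 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.415 with an estimated correlation), with Rhox6 3.44-fold and Rhox9 3.37-fold lower. The pluripotency list fell for 16 of 30 and rose for 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.415 with an estimated correlation), with Tcl1 2.89-fold lower. Endoderm genes fell for 8 of 19 and rose for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00678, adjusted p = 0.415 with an estimated correlation), with the transcription factor Gata6 2.68-fold and Amn, a membrane protein of visceral endoderm, 2.63-fold lower. Of the 2-cell-like genes 4 of 5 fell (4 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.415 with an estimated correlation), Tcstv3 by 3.20-fold (log2 -1.68, and -1.65 on a second probe). The list's call was lost in the deposited scaled values (adjusted p = 0.0686, 0.0182 to 0.415 over the settings tried). Fibroblast genes rose for 19 of 26 and fell for 0 (21 and 0 adjusted over the list alone, camera adjusted p = 1.33e-05, adjusted p = 0.415 with an estimated correlation), with Thbs2 2.17-fold and the collagen cross-linking enzyme Lox 1.77-fold higher. Cholesterol genes rose for 8 of 16 and fell for 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0487, adjusted p = 0.415 with an estimated correlation), with Hmgcs1 1.31-fold higher. This call was lost there too (0.0686, 0.045 to 0.415). The fibroblast list mean was 10.88 ± 0.40 in OSE and 10.21 ± 0.44 in OSK clones.

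Between OSE and OSK clones 4826 features (45.8%) changed, 2442 higher and 2384 lower, and 312 by at least 2-fold, 118 higher and 194 lower (109 and 186 at their bound). Median scaling gave 2989 higher and 1725 lower, and the deposited scaled values leaned the other way, with 1767 higher and 2483 lower. The number was 2189 with the Y-linked signal, which separates these sets without overlap, as a covariate, and 3031 with near-identical arrays averaged.

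The ES lines D3 and R1 were compared to give the scale of a difference between ES cells, and the lines also differed in medium. Among the largest falls in D3 cells, Mmp13 was at least 30.2-fold lower, the stromelysin Mmp3 at least 12.2-fold, the interferon-induced Ifi27 18.5-fold, the matrix protein Mgp 17.5-fold and Lgals3bp, a secreted glycoprotein, at least 9.14-fold lower. The chemokines Ccl7 and Ccl5 were 13.5-fold and at least 6.02-fold lower, and the matricellular Ccn5 at least 5.95-fold. Higher in D3 cells were the troponin Tnnt2 (4.36-fold, adjusted p = 7.78e-10), the endothelial protein Plvap (4.05-fold), the glutathione transferase Gstt2 (3.62-fold), the kinase Pim2 (3.40-fold), Dppa3 (3.21-fold), the phosphatase Dusp4 (2.79-fold) and the membrane protein Prom1 (2.77-fold), each in 2 of 2 D3 arrays against all 4 R1 arrays. The scaffold protein Pdzk1 was 2.87-fold higher (adjusted p = 0.0168) but did not pass without either D3 replicate (0.144 and 0.145), and over all settings tried its adjusted p ran from 6.45e-08 to 0.796. Of the factors none passed in the fit of all groups, with Tbx3 at -0.77 on the log2 scale (adjusted p = 0.0659), Klf4 at -0.34 (adjusted p = 0.57) and Pou5f1 at -0.12 (adjusted p = 0.78). Tbx3 passed with median scaling (-0.82, adjusted p = 0.0429), with these groups fitted alone (-0.77, 5.58e-06), with array weights (-0.77, 0.000214) and with the fibroblast signal as a covariate (-0.82, 0.0319). Klf4 passed with these groups fitted alone (-0.34, 0.00558) and Pou5f1 with the fibroblast covariate (-0.46, 0.00281). Over all settings tried the adjusted p ran from 5.58e-06 to 0.863 for Tbx3 and from 0.00281 to 1 for Pou5f1. Eif2s3y was above background in both lines, with a log2 difference of -0.65 (adjusted p = 0.375) that passed with these groups fitted alone (0.00014) and with array weights (0.0329).

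The interferon response fell in D3 cells for 7 of 18 genes and rose for 0 (9 and 0 adjusted over the list alone, camera adjusted p = 7.32e-12), and the call held with an estimated correlation (adjusted p = 0.000139), with Ifit3 at least 3.89-fold and Igtp at least 2.13-fold lower. Glycolysis and hypoxia genes fell for 12 of 19 and rose for 0 (16 and 0 adjusted over the list alone, camera adjusted p = 2.54e-15, adjusted p = 0.0985 with an estimated correlation), with the glucose transporter Slc2a1 2.67-fold lower. Fibroblast genes fell for 7 of 26 and rose for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 2.23e-08, adjusted p = 0.367 with an estimated correlation), with Lox 4.40-fold lower, and the list mean was 8.91 ± 0.01 in the D3 arrays. Genes of the primed epiblast, the stage after implantation, rose for 4 of 9 and fell for 0 (5 and 0 adjusted over the list alone, camera adjusted p = 0.000467, adjusted p = 0.201 with an estimated correlation), with the transcription factor Pou3f1 2.42-fold higher. The 2-cell-like genes fell for 2 of 5 (3 adjusted over the list alone, camera adjusted p = 0.00452, adjusted p = 0.201 with an estimated correlation), and cell cycle genes fell for 4 of 23 and rose for 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00912, adjusted p = 0.213 with an estimated correlation). Among the latter the kinase Plk1 was 6.01-fold and the inhibitor Cdkn2b 7.99-fold lower. The call of the cell cycle list was lost in the deposited scaled values (adjusted p = 0.0696, 0.00434 to 0.213 over the settings tried).

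In D3 cells 1025 features (9.7%) differed from R1 cells, 488 higher and 537 lower, and 221 by at least 2-fold, 38 higher and 183 lower (31 and 152 at their bound). The number was 315 without D3 replicate 1 and 362 without replicate 2, where the lone array is assumed to vary like the other groups, 3345 with these 2 groups fitted alone, and 59 with near-identical arrays averaged, which leaves 1 sample of each line. Of the 25 named genes that passed, 10 then no longer did: Gstt2, Pim2, Pdzk1, Dusp4, Prom1, Ccl7, Pou3f1, Nanog, Dlk1 and Cdkn2b. They had the same log2 differences and SEs 1.49 to 1.90 times as large. Median scaling called 30.9% of the changed features higher and the deposited scaled values 35.5%, against 47.6% here.

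The profile of each clone was then compared with that of R1 cells as a whole. Correlation across features with the R1 mean was 0.946 ± 0.005 in OSK (SD, n = 11), 0.946 ± 0.004 in OSKT (n = 11) and 0.933 ± 0.006 in OSE clones (n = 8), against 0.981 in D3 arrays and 0.997 among R1 arrays, each set against the other R1 arrays. Features are not independent replicates, so clones were the units of the test. OSKT and OSK clones did not differ (by -0.0001, 2-sided permutation p = 0.9529). OSE clones lay lower than OSK clones by -0.0132 (2-sided exact permutation p = 3.969e-05, adjusted p = 5.954e-05 over 3 tests) and lower than OSKT clones by -0.0131 (exact permutation p = 2.646e-05, adjusted p = 5.954e-05). These permutations and the linear model below count near-identical clones as separate units. Their p-values are too small to the extent that such clones are not independent. The fibroblast list mean was 10.88 in OSE, 10.21 in OSK and 10.09 in OSKT clones. Within sets this mean and the similarity correlated at -0.56 in OSE (p = 0.149), -0.42 in OSK (p = 0.199) and -0.44 in OSKT clones (p = 0.171), none past 0.05. In a linear model of the 30 clones with the sets as terms, the slope of similarity on the list mean did pass (-0.0056 per log2 unit, SE 0.0021, p = 0.0135). With this mean as a covariate in a linear model of the 30 clones, the difference of OSE from OSK clones went from -0.0132 (SE 0.0023) to -0.0094 (SE 0.0025, p = 0.0009), and that from OSKT clones from -0.0131 (SE 0.0023) to -0.0087 (SE 0.0027, p = 0.0032). With D3 cells as the reference neither passed (-0.0058, exact permutation p = 0.0615, and -0.0022, exact permutation p = 0.3734). The distance of each clone from the other clones of its set, as a root mean square log2 difference, averaged 0.257 ± 0.044 in OSK, 0.267 ± 0.043 in OSKT and 0.277 ± 0.109 in OSE clones, against 0.157 in R1 cells, and none of the 3 differences between sets passed (adjusted p = 0.8553 for each by permutation).

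**Figure D3:**
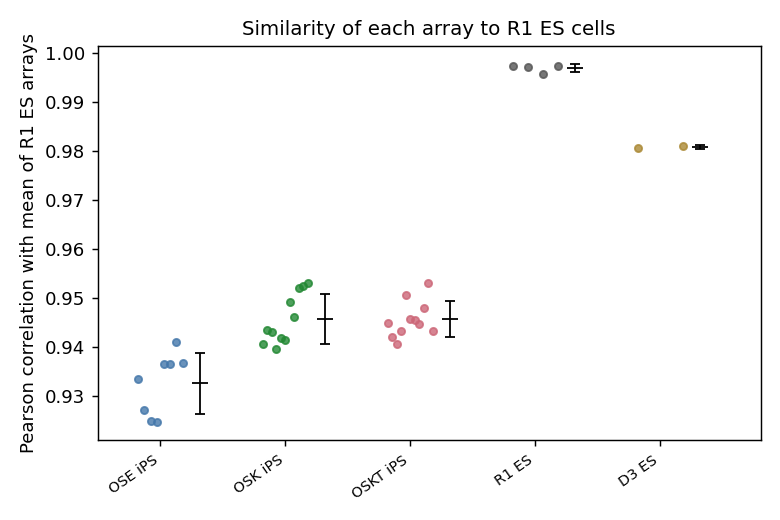
Each point is the Pearson correlation across 10533 features of 1 array with the mean of the R1 arrays (of the other R1 arrays for R1 itself), with the mean and SD of each group beside the points. All 30 iPS clones lie between 0.925 and 0.953, below the D3 arrays at 0.981, and the OSE clones reach from 0.925 to 0.941.

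A set of 70 features differed from R1 cells by at least 4-fold in the same direction in all 3 iPS sets, 30 higher and 40 lower, or 26 and 33 at their bound. Zfp42, Dppa3, Rpl29, Baiap2l1 and Spink10 were among them. The 3 comparisons share the R1 arrays, so they are not independent. With simulated sets that did not differ from R1 cells, the highest number in 20 simulations was 0. Independent noise could hardly give a 4-fold change, so this outcome was near fixed. With R1 arrays split between comparisons in 3 ways the number was 65 to 74. That split could not remove the sharing: the R1 arrays are near-identical, OSK and OSE clones were set against the same part, and adjusted p came from the fit of all arrays. D3 cells were changed in the same direction as the iPS clones for 23 of the 70, of which 21 were lower.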

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

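The tests of a strain variant and of fibroblast RNA below, those of clone numbers and of a shift shared by clones 5 to 11, that of admixture, both tests of a dim array and the splits of clusters were chosen after the result was seen, and array scaling, gene clusters and other splits of the samples were planned before. The test of a shared shift and that of features as bright as Eif2s3y were added once the first tests, of clone numbers and of a dim array, had come out on the side of a technical cause. Both replace a first form whose outcome was fixed, by the equal clone numbers of the sets or by quantile normalization.

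Single samples stood apart from the others of their group, by the gap to the nearest value relative to the group's range in OSE clones and R1 arrays, for 21 of 258 tested values, where chance gives about 1 in 20 groups (12.9). Among OSE clones, clone 8 had a root mean square difference from its set of 0.535 (others 0.199 to 0.314), an X-linked over autosomal median of -0.064 (others 0.046 to 0.134), and on the log2 scale Sugt1 at 8.39, Kpna3 at 8.70, Eif2s3y at 8.75, Eif3j1 at 9.06, P4ha2 at 10.05, Amn at 9.21 and Cdkn2b at 10.43. Clone 7 had Cdkn1c at 9.87 (others 12.12 to 12.69) and Dppa3 at 11.92 (others 11.26 to 11.51), and clone 1 had Xlr3b at 8.29 (others 5.85 to 6.68) and Mgp at 11.67 (others 10.48 to 11.02). Among R1 arrays, replicate 3 had a correlation with the others of 0.9957 (others 0.9973 to 0.9975), a root mean square difference of 0.189, a 75th percentile of 666.3 intensity units (others 533.3 to 554.9), Efhc2 at 10.53, Gata6 at 8.33 and Dnmt3b at 12.63. Replicate 4 had Tfap2c at 10.51 and replicate 2 had Socs2 at 13.15.

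OSE clone 8 read 8.75 for Eif2s3y, the Y-linked gene, against 10.75 in the other OSE clones. An admixture of cells like the OSK clones, in which Erdr1, Olfr887 and Olig1 are near background, would lower these genes too, but they were higher by 0.74 on average (log2). Clone 8 was the dimmest OSE array (75th percentile 337.3, others 462.5 to 617.3), so a dim array could be a cause. In the unscaled signals Eif2s3y was lower by 2.81 (log2), while the 1198 features about as bright were lower by a median of 0.51 (SD 0.57) and 12 of them (1%) by as much, which argues against dimness as the whole cause. A loss of the Y chromosome in part of this clone may be a hypothesis, which the Y-linked probe of Kdm5d leaves open: it read -1.5 intensity units in clone 8 (21.5 to 186.7 in the others) but was above background in clone 7 alone. The Kdm5d probe also read -34.3 to -0.1 in R1 and -28.5 to -14.1 in D3 cells, where Eif2s3y was above background. A low value of this probe therefore does not show that the Y chromosome is missing. Erdr1, of the pseudoautosomal region, was higher by 0.93 (log2) in clone 8 (SD of the other OSE clones 0.30), which this hypothesis does not account for. It was not tested further.

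Genes on the X chromosome were higher in OSKT than OSK clones. The measure sets X-linked against autosomal genes within each array, so a shift of a whole array cancels by construction and was not tested. Over 4 other settings the smallest difference was 0.20, and in 1 of them, the deposited scaled values, it was 0.27. This argues against scaling that varies with intensity. A few gene clusters are argued against by a median of at least 0.15 in each part of the chromosome. The difference was 0.03 within clones 1 to 4, so it follows the clone numbers, and the pooled value could stand for clones 5 to 11 alone, in which it was 0.31. A shift of clones 5 to 11 shared by both sets would leave the difference alike in both ranges, and is argued against by the change of 0.28 between them. Its permutation p of 0.0003 counts near-identical clones as separate units, among them all of OSK clones 1 to 4, and the ranges were set after the values were seen. How firmly the change stands is therefore not known. Both sets contributed to it: the mean fell from 0.26 to 0.16 between the ranges in OSK clones and rose from 0.29 to 0.47 in OSKT clones. The fibroblast list mean was also lower in clones 5 to 11 than in clones 1 to 4 of both sets. The labels do not say what sets clones 5 to 11 apart, so an effect of Tbx3 and a batch or a parental culture of OSK or OSKT clones stay open. No biological explanation was tested. The number and state of the X chromosomes in each clone were not measured, and no X inactivation gene could be tested, so these stay open too.

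For the 70 features at least 4-fold apart from R1 cells in all 3 iPS sets, fibroblast RNA in the R1 samples could be a cause, and is argued against as the whole cause by the fibroblast list, at least 0.37 higher (log2) in each iPS set than in R1 cells. It stays open for part of the 40 lower features, since 21 of them were also lower in D3 cells, where the list averaged 8.91 against 9.72 in R1 cells. A strain or donor variant under the probe cannot be told apart from a change in expression, since 0 of the 70 had another probe above background. The genetic background of the iPS cells and that of R1 cells stays open as an untested difference.

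Other splits of the same arrays, 100 drawn with the real one, gave a count of changed features as large in 1 of 100 (the real one) for each of the 5 comparisons of groups of at least 4, so chance is excluded at that level as far as single arrays are independent units. These splits ignore near-identical arrays and the clone ranges. The real and the highest other counts were 3741 and 1 for OSKT with OSK, 5664 and 3655 for OSK with R1, 5724 and 3424 for OSKT with R1, 6179 and 4686 for OSE with R1, and 4826 and 2099 for OSE with OSK. The cause of the high counts in other splits was not tested, and the median of the other splits was 0. With each cluster of near-identical arrays averaged, and clusters exchanged within clones 1 to 4 and within clones 5 and above, 1 of 100 splits (the real one) gave a count as large for OSKT with OSK (1362, highest other 691) and for OSE with OSK (3031 and 1147). R1 cells are 1 such cluster, which leaves 7 splits for OSK, 7 for OSKT and 6 for OSE clones with R1, too few for a share under 0.05. The real and the highest other counts there were 2391 and 0, 2454 and 19, and 2921 and 388.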

How the results depend on the processing

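Placeholder probes kept, near-identical arrays averaged, the clone-number settings, X-linked features left out and the fibroblast covariate for similarity were chosen after the data were seen, and the other settings were planned.

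Of 222 named gene results, 133 kept their direction and their side of the threshold in every setting run, and of 6799 values 6656 did so, with 107 that no longer passed, 21 that newly passed and 15 that changed sign. The scaled table, median scaling, no background correction, no filter, a stricter filter and every probe as a feature changed 1, 5, 1, 1, 0 and 0 of them, and none changed sign there. Under the stricter filter only 198 of the 222 could be read. The cause was not tested except where stated.

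With the Y-linked signal as a covariate, which is Eif2s3y alone and was itself at least 3.47 higher (log2) in OSE than OSK clones, so that by construction it takes up part of the comparison, 2189 features changed between OSE and OSK clones, and the log2 difference changed sign for Csrp1 (-0.45), Pou5f1 (0.59), Esrrb (0.13), Tcl1 (0), Kit (0.68), Lox (-0.01), Thbs2 (-0.15), Amn (0.41), Ndrg1 (0.14) and P4ha2 (0.12), none of them past the threshold. Tbx3 (-1.11), Klf4 (-0.73) and Sox2 (-0.24) kept their sign and did not pass, so that no factor gene passed there. In all, 24 of the 36 named genes that passed between OSE and OSK clones no longer did, Eif2s3y by construction. Others among them were Smc1b (-0.03), Dmrtc1c1 (-0.50) and Abhd16a (0.97). Klf4 and Sox2 did not pass in OSK (-1.50 and -0.76) or OSKT clones (-1.34 and -0.75) against R1 cells either, while Pou5f1 passed in OSKT clones (-1.11). Ndrg1 also changed sign against R1 cells in OSK (-0.50) and OSKT clones (-0.51). Within clones 1 to 4 alone, with fewer samples, 1282 features changed between OSKT and OSK clones, with Cdkn1c at 0.38, Zfp352 at -0.07 and Tcstv3 at -0.01 of opposite sign, none past the threshold.

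Near-identical arrays averaged, which by construction leaves 19 samples with R1 and D3 cells as 1 each, gave 1362 changed features for OSKT with OSK, 2391 for OSK with R1, 2454 for OSKT with R1, 2921 for OSE with R1, 3031 for OSE with OSK and 59 for D3 with R1. For D3 with R1 the number was 3345 with only these groups, 3432 with array weights and 2798 with the fibroblast covariate.

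Leaving out 1 array at a time gave 3377 to 3866 changed features for OSKT with OSK, 5150 to 5695 for OSK with R1, 5206 to 5738 for OSKT with R1, 5696 to 6390 for OSE with R1, 4358 to 5383 for OSE with OSK, and 315 (without D3 replicate 1) to 859 for D3 with R1, with 362 without D3 replicate 2, where the lone array is assumed to vary like the others. With replicate number as a block the counts were 4315, 6231, 6239, 6695, 4898 and 1160, in the order OSKT with OSK, OSK, OSKT and OSE with R1, OSE with OSK, and D3 with R1. The block ended the call of glycolysis and hypoxia genes in OSK and OSKT against R1 and gave one to fibroblast, mesoderm and streak, and primed epiblast genes there, to the last 2 and DNA methylation genes in OSE against R1, and to primed epiblast and stress response genes in OSE against OSK.

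With an estimated correlation the number of lists past the threshold was 0 for OSK with R1, 1 for OSKT with R1, 1 for OSE with R1, 0 for OSE with OSK and 1 for D3 with R1, against 7, 7, 7, 8 and 6. Similarity to D3 instead of R1 cells differed by -0.0058 between OSE and OSK (exact 2-sided permutation p = 0.0615) and by -0.0022 between OSE and OSKT clones (exact p = 0.3734), while leaving out 1 clone gave -0.0144 to -0.012 and -0.0142 to -0.0119. OSKT and OSK clones differed by -0.0009 to 0.0006 with 1 clone left out. The spread between clones, not different in any setting, ran with 1 clone left out from 0.001 to 0.0173 for OSKT minus OSK, from -0.0286 to 0.0365 for OSE minus OSK and from -0.0378 to 0.0273 for OSE minus OSKT, and the negative values came from leaving out OSE clone 8. A slide block was not run, since no slide is given. Signal over background limits the rest: 10572 of 18720 measured probes passed the filter, and 0 of the X inactivation genes.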

Other observations

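All values here were examined after the data were seen, with lists and tests that were planned.

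Imprinted genes outside the Dlk1-Dio3 region moved both ways in OSKT against OSK clones, with 3 of 22 higher, 6 lower and 13 not past the threshold. The amino acid transporter Slc38a4 was 1.62-fold lower (adjusted p = 5.27e-08 from limma, 11 of 11 clones below the OSK mean), while Usp29 was at least 1.39-fold and the splicing-related Snrpn 1.27-fold higher, which within clones 1 to 4 did not pass (log2 0.31 and 0.04). Igf2, a growth factor, was 12.9-fold higher in OSK clones than in R1 cells. Of genes of DNA methylation and Polycomb repression 5 of 14 were higher and 4 lower in OSKT clones, with a median of 0, a mean of -0.03 and an upward direction in camera (adjusted p = 0.994). The maintenance methyltransferase Dnmt1 was 1.37-fold and its partner Uhrf1 1.21-fold lower, and the Polycomb protein Cbx2 1.32-fold higher. Targets of LIF and Stat3 fell for 5 of 17, with Socs2 1.23-fold and Egr1 1.53-fold lower. Cell cycle genes rose for 5 of 23 and fell for 1, with Cdk1 1.18-fold higher, and p53 targets fell for 6 of 17 and rose for 1. With near-identical arrays averaged Socs2 (log2 -0.24), Egr1 (-0.65) and Cdk1 (0.20) did not pass, nor did Socs2 with median scaling (-0.21). None of these lists passed as a set in camera (adjusted p = 0.389 for imprinted genes, 0.247 for LIF targets, 0.389 for the cell cycle and 0.358 for p53 targets).

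Genes of the primed epiblast rose in OSE clones against R1 cells for 7 of 9 and fell for 1 (camera adjusted p = 0.0548, but 0.00318 with replicate number as a block, 0.00318 to 0.473 over the settings tried), with Pou3f1 and the methyltransferase Dnmt3b 2.27-fold higher each. Mesoderm and primitive streak genes rose for 8 of 18 and fell for 3 (camera adjusted p = 0.147, but 0.00384 with the block, 0.00384 to 0.766 over the settings tried). Among them the growth factor Fgf8 was at least 5.31-fold higher, but its log2 difference of 3.57 (SE 0.78) became 0.09 (SE 0.55) with the fibroblast signal as a covariate and 3.09 (SE 1.44) with near-identical arrays averaged, and passed in neither. Neural ectoderm genes rose for 3 of 7 and fell for 1 (camera adjusted p = 0.325). Interferon genes in OSK clones rose for 4 of 18 and fell for 8 against R1 cells (camera adjusted p = 0.262). In D3 cells Nanog, a factor of the pluripotency network, was 1.95-fold lower and Dlk1 2.08-fold higher than in R1 cells, in 2 of 2 arrays, and neither passed with near-identical arrays averaged. No X inactivation gene and 1 Y-linked gene, Eif2s3y, could be tested.

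OSK clone 1 was the 1 OSK clone with Eif2s3y above background. Its unscaled signals were 129.5 for Eif2s3y, 227.1 for Erdr1, 145.6 for Olfr887 and 264 for Olig1.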
